A study of Mus musculus with 12 samples.

How the data were processed

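Gene expression was measured in mouse embryonic stem cells (ESC) on 12 Affymetrix MoGene ST arrays, which carry probes along the exons of each gene. Per the labels, a cell line lacking the BMP receptor gene Bmpr1a and marked with green fluorescent protein (GFP) was compared with unmarked wild-type cells. The 2 lines were cultured in N2B27, a serum-free medium, either mixed together for 3 days or each alone. The mixed populations were separated by fluorescence-activated sorting on GFP before RNA was extracted. The labels give 4 groups of 3 arrays: mixed Bmpr1a-/-, separate Bmpr1a-/-, mixed wild-type and separate wild-type. Whether the separate cultures also went through the sorter is not given in the sources used here. Genotype goes with the cell line and with the GFP mark in every array, so no comparison between genotypes separates these.

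Per the file headers and the submitters' notes, the authors normalized the arrays with RMA in Affymetrix Expression Console 1.2. RMA corrects the background, matches the distributions of the arrays (quantile normalization) and summarises the probes of each probe set. The deposited series table held log2 values centred per probe set on the median of the authors' samples. The same headers name 1 further array of another day, which the authors left out for a problem with its file. A deposited workbook held the same values (largest difference 5e-07) and, on another sheet, linear intensity values that the authors called raw. On the log2 scale that sheet differed from the series table by a constant within each probe set (largest spread 2.2e-06), so it held RMA signal rather than unprocessed intensities. The authors' centring point equalled the median of these 12 arrays, within 0.0001, for 3% of probe sets, and cancels in every difference between groups. The design had assumed values with a level in the series table. Because centred values carry none, the level used to filter probe sets and to choose among them came from the log2 of the linear sheet. Detection calls were not used here. The array medians of signal lay between 51.6 and 54.3 and the upper quartiles between 166 and 180.25, so the distributions were not matched exactly. The upper quartiles were 177.08, 167.62 and 169.89 in mixed and 176.79, 178.42 and 170.56 in separate Bmpr1a-/- cells. Pairs of arrays correlated between 0.9799 and 0.9981 across probe sets, and no pair was identical.

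Of 28815 probe sets, 22731 had 1 gene symbol, 2447 had several and 3637 had none. The 22731 symbols were matched to a RefSeq gene table of assembly GRCm38.p6. Of these, 16851 were current, 3893 were updated through a synonym or identifier and 1987 were kept as in the file. Probe sets with a mean signal under the 20th percentile of the table (25.3) were left out. The probe set with the highest mean signal stood for each gene, which left 17639 genes. Probe sets with several symbols were tested apart.

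Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3. The groups shared 1 estimate of the spread per gene (8 residual degrees of freedom), which eBayes moderated to a median of 12.7 in total. There were 5 contrasts: mixed against separate culture within each genotype, the difference between those 2 changes (the interaction), and Bmpr1a-/- against wild-type cells within each kind of culture. A gene passed at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Changes are given on the log2 scale with their standard error (SE), and group levels as mean signal with SD (n = 3).

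From general knowledge, 32 lists of genes with 1044 entries (977 distinct symbols) were written before the files were opened. Of these, 31 were tested, each with at least 5 measured members, by limma's camera at its preset correlation of 0.01. Camera compares the genes of a list with all other genes. The test was repeated with the correlation estimated per list (statmod 1.5.0), and with fry, which asks whether the members of a list move one way on balance. Adjusted p-values of lists are over the 31 lists of a contrast. The remaining list held sex-linked genes and served to describe the lines.

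Genes were named in the text by a rule. Bmpr1a came first. Per contrast the rule then took the 10 largest rises and 10 largest falls among genes that passed and whose 3-array ranges did not overlap. It left out symbols of the form Gm plus digits, ending in Rik, or starting with Olfr, Vmn, Mir, Snor, Rps or Rpl, unless in a list. Other loci without a proper name, such as LOC620963 and BC147527, stayed in. Where fewer than 10 genes passed, the rule took the 10 smallest p-values. The 4 members of each list with the largest difference and a fixed set of regulators completed the rule. Nanog, one of the fixed set, was represented only by a probe set shared with a pseudogene and was outside the tested genes. The comparisons and their tests, the naming rule, the lists and most alternatives were set before the data were examined. Some tests of explanations were added later, as stated where they are given.

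The labels number the replicates 1 to 3 in every group, and header rows of the workbook number them as experiments (exp) in the same way in all 4 groups. Neither says whether equal numbers share a day or a culture. Deviations from the group means correlated, for arrays of equal number, at 0.39, 0.15 and 0.37 between mixed and separate Bmpr1a-/- cells. They correlated at 0.64, 0.38 and 0.42 between the 2 mixed populations. For both of these pairs of groups all 3 values were above 0.1, the bound set for speaking of pairing, and values with the replicate number as a block are given where they change a call or move a count beyond 1.5 times. The p-values measure only the spread between these arrays, and the labels do not say that the replicates were separate cultures. The number of arrays limits the precision.

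The fit was tested on simulated data with the measured spread of each of the 17639 genes, 100 of them changed by 0.5 and 100 by 1 on the log2 scale. For the co-culture contrast in Bmpr1a-/- cells it recovered 70 and 95 of these, with 10 false calls. The same contrast in wild-type cells gave 50 and 98 with 8 false calls, and the interaction gave 44 and 90 with 15. For the genotype contrast in separate culture it recovered 63 and 98 with 9 false calls, and in mixed culture 71 and 99 with 10. No direction was wrong, and no gene was called when nothing was changed. With nothing changed camera called 0 lists in 4 of the contrasts and 1 in the interaction. The simulated genes varied independently of each other. These runs therefore do not show how camera or the gene counts behave where genes move together. Alternatives covered the source table, the scaling, the filter, the probe sets per gene, the arrays in the fit, the replicate block, the variance model, array weights, a minimum fold, the set test and leaving out each array in turn. The values of a few single genes of the lists are not reported here; the counts and tests of the lists include them.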

Results

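The arrays addressed how Bmpr1a-/- ESC, which lack a receptor for bone morphogenetic proteins (BMP), and wild-type ESC differ in expression when they share a culture and when each grows alone. Bmpr1a itself gave a mean signal of 370 ± 9.96 (SD, n = 3) in mixed Bmpr1a-/- cells and 434 ± 25 in separate Bmpr1a-/- cells. It gave 524 ± 27 in mixed and 549 ± 33.8 in separate wild-type cells. The 6 Bmpr1a-/- arrays spanned 362 to 462 and the 6 wild-type arrays 505 to 588. The difference was -0.34 (SE 0.07, adjusted p = 0.0091) in separate and -0.50 (SE 0.07, adjusted p = 0.00043) in mixed culture. How the probes lie relative to the deleted part of the gene is not given in the sources used here, so the level is a weak check of the labels. In neither genotype did Bmpr1a pass the test between mixed and separate culture (-0.23, adjusted p = 0.13 in Bmpr1a-/- cells and -0.07, adjusted p = 1.0 in wild-type cells).

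In Bmpr1a-/- cells, co-culture with wild-type cells came with lower expression of Fst, Nodal, Eomes and Myc. Fst, which encodes follistatin, a secreted inhibitor of activin and BMP ligands, fell by 2.40 (SE 0.23, adjusted p = 0.0016), from a signal of 601 ± 261 to 108 ± 11.9 (n = 3 each). Nodal, a ligand of the TGF-beta family that maintains the epiblast, fell by 1.30 (SE 0.18, adjusted p = 0.006), from 352 ± 71.8 to 145 ± 40.7. Eomes, a T-box transcription factor of trophoblast and primitive streak, fell by 1.28 (SE 0.18), from 153 ± 58.3 to 60.5 ± 3.68. Myc, which drives growth and ribosome production, fell by 1.13 (SE 0.15, adjusted p = 0.0049), from 201 ± 53.1 to 90.7 ± 10.3. In wild-type cells the signal of Myc was 88 ± 9.15 alone and 101 ± 7.5 mixed, and that of Fst 89.8 ± 14 and 97.7 ± 9.7.

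The other large falls were in Ppp4r4, a regulatory subunit of protein phosphatase 4 (-1.49, SE 0.15), Trh, the precursor of thyrotropin-releasing hormone (-1.25, SE 0.28), and the neurofilament gene Nefl (-1.23, SE 0.14). The growth factor gene Fgf15 (-1.16, SE 0.18), the ephrin receptor gene Epha1 (-1.15, SE 0.16) and the cell adhesion gene Nrcam (-1.09, SE 0.13) completed the 10 largest. The largest rises were in Bhlhe41, a transcriptional repressor tied to circadian rhythm (1.25, SE 0.18), Fabp3, which binds fatty acids (1.22, SE 0.20), and Aqp3, a channel for water and glycerol (1.17, SE 0.17). Lrrc31 (1.17), LOC620963 (1.14) and BC147527 (1.08) followed, none of them well described. Smc1b, a cohesin subunit of meiosis (0.99), the tight junction gene Cldn4 (0.97), Ifi30, a thiol reductase of lysosomes (0.91), and Tdpoz3 (0.91), of a family expressed in early embryos, completed the 10 largest rises.

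Of 44 measured genes of the lysosome and of autophagy 8 rose, none fell and 36 did not pass (25 rose and 1 fell adjusted over the list alone), with a median of 0.32. Camera put the list above other genes (adjusted p = 1.4e-17), a call lost at adjusted p = 0.074 with an estimated correlation. By fry, which does not compare the list with other genes, adjusted p was 0.0098. Hexa, a subunit of the lysosomal hexosaminidase, rose by 0.82 (SE 0.15, adjusted p = 0.017), from 400 ± 80.5 to 699 ± 86. The lysosomal membrane gene Lamp2 rose by 0.74 (SE 0.17) and the sialidase gene Neu1 by 0.62 (SE 0.11), while Cd63 (0.68, adjusted p = 0.061) did not pass.

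Of 18 targets of FGF and ERK signalling 9 fell and 9 did not pass (11 fell adjusted over the list alone), with a median of -0.63. Among them the ETS factors Etv4 and Etv1 changed by -0.96 and -0.81, and the epiblast growth factor gene Fgf5 by -0.95 (SE 0.15, adjusted p = 0.011), from a signal of 480 ± 90.8 to 248 ± 42.7. Of 29 genes of the primed epiblast, the state after implantation, 6 fell, none rose and 23 did not pass (17 fell adjusted over the list alone), with a median of -0.38, and they included Nodal, Fgf15, Etv4 and Fgf5. Of 37 genes of ribosome production under Myc 4 fell and 33 did not pass (18 fell adjusted over the list alone), with a median of -0.24. Myc and Bop1 (-0.48), a ribosome assembly factor, were among the 4, while Mycn (-0.58, adjusted p = 0.14) did not pass. Of 19 WNT targets 5 fell, 1 rose and 13 did not pass (9 fell and 1 rose adjusted over the list alone). They included T (-0.85), the brachyury gene of the primitive streak, and Wnt3 (-0.84), a ligand needed for the streak, and the median was -0.26. The FGF and ERK list shares 3 genes with the primed list, 2 with the WNT list and 1 with the Myc list. Camera's adjusted p was 1.5e-12 for the FGF and ERK list, 4.3e-14 for the primed list, 9.2e-13 for the Myc list and 2e-06 for the WNT list. The WNT call was lost, with adjusted p = 0.08 with an estimated correlation, while fry gave adjusted p = 0.0051. Adding the block for replicate number gave adjusted p = 0.073 with an estimated correlation for the FGF and ERK list and 0.063 for the Myc list.

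Of 29 genes of the naive state, the state before implantation, 1 rose, Esrrb (0.73, SE 0.15, adjusted p = 0.031), and 28 did not pass (6 rose adjusted over the list alone), with a median of 0.22 (adjusted p = 3.3e-06, and adjusted p = 0.15 with an estimated correlation). Fbxo15 (0.95, adjusted p = 0.10) and Pou5f1, which encodes the pluripotency factor Oct4 (-0.22, adjusted p = 0.23), were among those that did not pass. Of 9 measured genes of the 2-cell embryo 1 rose, Tdpoz4 (0.81, SE 0.16), and 8 did not pass (6 rose adjusted over the list alone), with a median of 0.24 (adjusted p = 1.2e-05). Of 18 germ cell genes 1 rose, the meiotic gene Hormad1 (0.59), and 17 did not pass (1 rose adjusted over the list alone). The germ cell median was 0.14 (adjusted p = 0.00081, and adjusted p = 0.41 with an estimated correlation). The meiotic gene Sycp3 (0.93, adjusted p = 0.13) did not pass.

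Of 42 measured targets of the tumour suppressor p53, 3 fell and 39 did not pass (10 fell adjusted over the list alone), with a median of -0.07 (adjusted p = 0.015, and adjusted p = 0.59 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, fell by 0.62 (SE 0.11, adjusted p = 0.016), from a signal of 516 ± 55.1 to 336 ± 39.6, and the kinase gene Plk2 fell by 0.48 (SE 0.11). Trp53, the p53 gene itself (-0.24, adjusted p = 0.23), Mdm2, its negative regulator (-0.40, adjusted p = 0.14), and Ccng1 (-0.13, adjusted p = 0.33) did not pass. Of 36 genes of the apoptosis machinery none passed, among them Dffb (-0.51, adjusted p = 0.094) and Bax (-0.22), and the list was not called (adjusted p = 0.18). The 29 genes of DNA damage signalling gave no call (adjusted p = 0.98), with a median of -0.05, a mean of -0.01 and a test direction of higher, and none of them passed.

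BMP and mTOR genes showed few changes. Of 27 BMP targets 1 fell, Smad7, an inhibitor of TGF-beta and BMP signalling (-1.02, SE 0.11, adjusted p = 0.0022), and 26 did not pass (2 fell and 3 rose adjusted over the list alone). Of the Id genes, which BMP induces, Id1 (-0.21), Id2 (-0.80, adjusted p = 0.055) and Id3 (-0.30) did not pass. The BMP list was not called (adjusted p = 0.49). Of 35 genes of the mTOR pathway 2 rose and 33 did not pass (3 rose and 3 fell adjusted over the list alone), and the list was not called (adjusted p = 0.72). The 2 were Tsc1, an inhibitor of mTORC1 (0.51), and Rragc, a GTPase that recruits it to lysosomes (0.48). Mtor (-0.04), Ddit4 (0.03) and Sesn2 (-0.46, adjusted p = 0.11) did not pass.

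Further lists covered metabolism, the cell cycle, stress and other lineages. None of the 31 cholesterol and lipid synthesis genes passed over all genes (4 fell adjusted over the list alone), and Hsd17b7 (-0.44) and Fasn (-0.38) came nearest. Their median was -0.20 (adjusted p = 1.2e-05, and adjusted p = 0.41 with an estimated correlation). Of 31 S phase genes 2 fell, Ccne2 (-0.49) and Ccne1 (-0.40), with a median of -0.12 (adjusted p = 0.014, and adjusted p = 0.61 with an estimated correlation). Of 30 primitive streak genes 3 fell, Eomes, T and Wnt3, with a median of -0.08 (adjusted p = 0.012, and adjusted p = 0.54 with an estimated correlation). In both lists the count adjusted over the list alone was the same. Of 22 trophoblast genes 1 fell, Eomes, while the median was 0.15 (adjusted p = 0.0035, and adjusted p = 0.41 with an estimated correlation). No member passed over all genes in 4 further called lists. They were G2 and M phase (median 0.08, adjusted p = 0.012, and adjusted p = 0.65 with an estimated correlation), respiration (-0.10, adjusted p = 0.014, and adjusted p = 0.69 with an estimated correlation), the unfolded protein response (-0.08, adjusted p = 0.02, and adjusted p = 0.41 with an estimated correlation) and hypoxia (0.08, adjusted p = 0.021, and adjusted p = 0.41 with an estimated correlation). Adjusted over the list alone, 3 genes of the unfolded protein response fell and 1 rose, and none passed in the other 3 lists. Glycolysis was not called (adjusted p = 0.05), though 2 of its 21 genes rose, Eno2 (0.72) and Pfkp (0.60). It was called with the block (adjusted p = 0.039) and without mixed wild-type replicate 1 or 3, mixed Bmpr1a-/- replicate 2 or separate replicate 1 or 3 (down to 0.0044). None of 29 genes that respond to cell dissociation and sorting passed (Fos -0.58, SE 0.43), and that list was not called (adjusted p = 0.57). Without a call, the imprinted list held a gene that rose, Igf2r (0.76), and the interferon list held B2m (0.80), the light chain of MHC class I, and the RNA sensor gene Ddx58 (0.50).

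**Figure D1:**
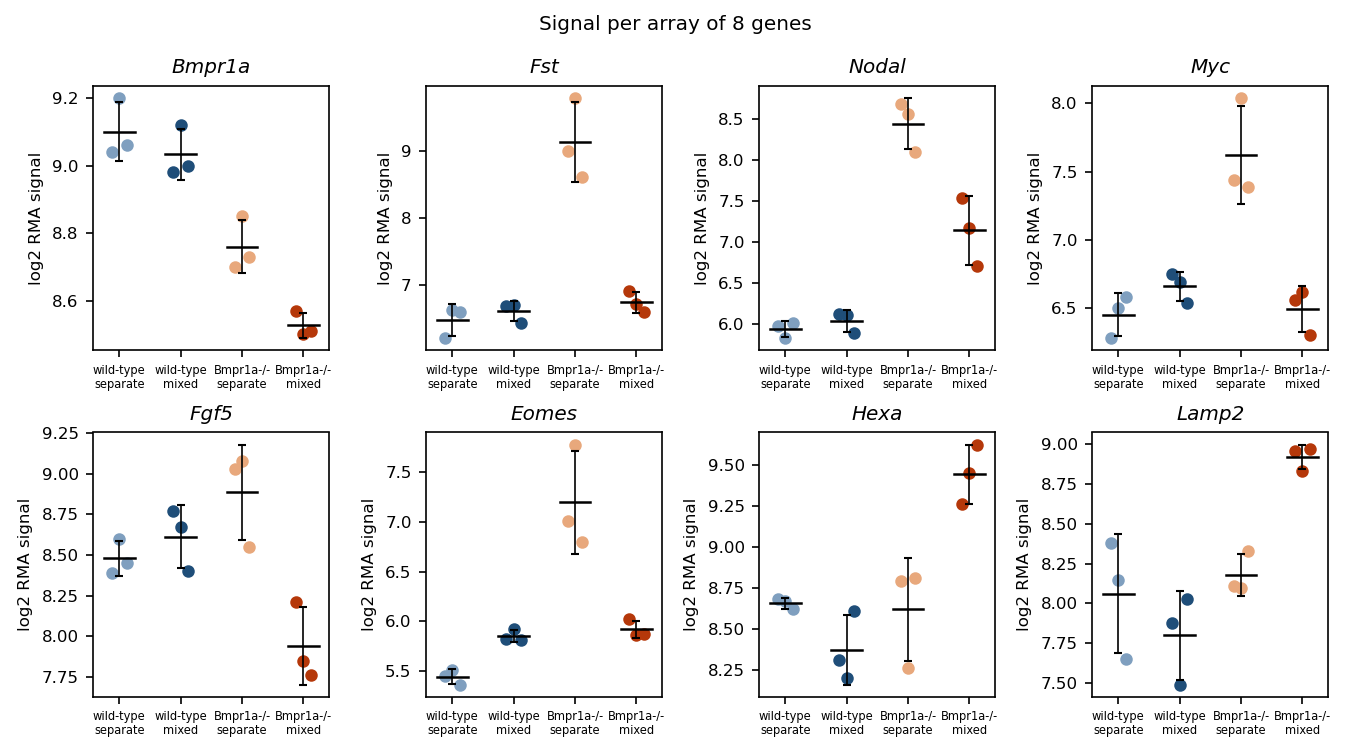
Signal on each array (log axis) of 8 genes in the 4 groups of 3 arrays, with points for arrays, lines for group means and error bars of 1 SD. Fst lay at 392 to 893 in separate Bmpr1a-/- cells and at 97.3 to 121 in mixed Bmpr1a-/- cells, near the wild-type range of 73.7 to 104.

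By limma, 279 of 17639 genes passed in this comparison, 139 higher and 140 lower in co-culture, and 2630 had an unadjusted p under 0.05. In all 279 the 3 mixed arrays lay on one side of the 3 separate ones, which chance gives 10% of genes and 18.0% of all genes showed. The median size of the change was 0.50, and 19 genes changed at least 2-fold. Camera called 17 of 31 lists. With an estimated correlation 4 calls held: FGF and ERK targets, primed epiblast, Myc and ribosome production, and the 2-cell embryo (adjusted p = 0.032 each). The count was 50 without mixed Bmpr1a-/- replicate 2, 70 without mixed replicate 3, 130 without separate replicate 1 and 73 without separate replicate 2. It was 879 with the replicate block, which kept all 279 and with which Cd63, Mycn, Fbxo15, Sycp3, Mdm2, Dffb, Id2, Sesn2, Hsd17b7, Fasn and Fos passed as well. Of the 44 named genes that passed, 14 passed whichever array was left out: Fst, Ppp4r4, Nodal, Eomes, Nefl, Epha1, Myc, Nrcam, Smad7, Etv4, Bhlhe41, Aqp3, LOC620963 and BC147527. Each of the others, Cdkn1a, Fgf5, Hexa, Esrrb and T among them, lost its call without mixed Bmpr1a-/- replicate 2 or 3, and most also without separate replicate 1 or 2, with a highest adjusted p between 0.05 (Fgf15) and 0.19 (Trh).

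Of the 17 list calls, those for the lysosome, primed, FGF and ERK, Myc, WNT, naive, 2-cell, cholesterol and germ cell lists held whichever array was left out. Without mixed Bmpr1a-/- replicate 3 or separate replicate 2 the p53 call ended (adjusted p up to 0.2), as did that for G2 and M phase (up to 0.17). Without separate replicate 2 the hypoxia call ended (0.17), and without separate replicate 2 or 3 that of the unfolded protein response (up to 0.067). The respiration call ended without mixed replicate 2 or 3 or separate replicate 1 (up to 0.21), and the S phase call without mixed replicate 3 or separate replicate 1 (up to 0.057). The trophoblast call ended without mixed replicate 2 (0.34) and the primitive streak call without mixed replicate 1 (0.10). In none of the called lists did median, mean and test differ in sign.

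**Figure D2:**
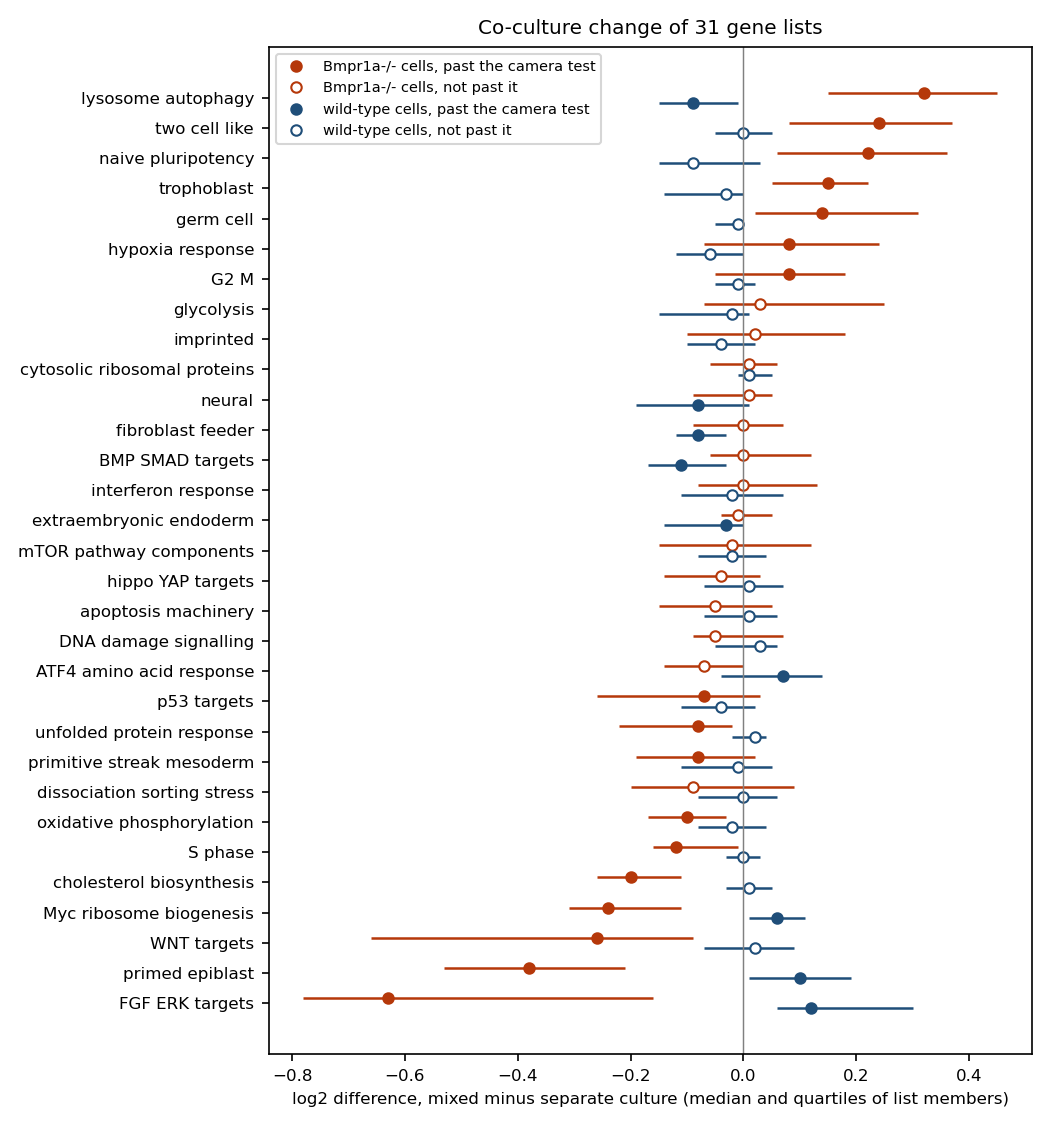
Median log2 change from separate to mixed culture of each gene list (vertical axis) in Bmpr1a-/- and wild-type cells, with points for medians and lines from the first to the third quartile of the members, and filled points where camera called the list. The lysosome list had a median of 0.32 in Bmpr1a-/- cells and -0.09 in wild-type cells, and the FGF and ERK list -0.63 and 0.12.

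In wild-type cells no gene passed between mixed and separate culture. Map3k5, a kinase of the stress response, came nearest (0.55, SE 0.07, adjusted p = 0.07), followed by Galnt3, which starts O-linked sugar chains (0.48), Ugt8a (0.43), the laminin gene Lamb2 (-0.30), L1td1, an RNA-binding gene of pluripotent cells (0.41), and Skil, which restrains TGF-beta signalling (0.35). Slc35d3 (0.50), Pdzd4 (0.33), Mertk (0.31) and Mmp25 (0.28) completed the 10 smallest p-values. Myc (0.21), Pou5f1 (0.32), Sox2 (-0.40), Cdkn1a (-0.12) and Mdm2 (-0.03) did not pass (adjusted p = 1.0 each). Pou5f1 gave a signal of 2210 ± 105 mixed and 1780 ± 159 alone, and Cdkn1a 326 ± 31.5 and 353 ± 26.2.

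Small shifts of whole lists appeared by camera in 9 of 31 lists, none with a member that passed over all genes and none called with an estimated correlation or by fry. FGF and ERK targets were higher (median 0.12, adjusted p = 5.7e-06, and adjusted p = 0.46 with an estimated correlation), with 3 of 18 higher adjusted over the list alone and Etv4 (0.49), Etv5 (0.46) and Dusp6 (0.34) in front. Primed epiblast genes were higher (median 0.10, adjusted p = 7.1e-06, and adjusted p = 0.46 with an estimated correlation), as were genes of ribosome production under Myc (0.06, adjusted p = 0.00021, and adjusted p = 0.47 with an estimated correlation). BMP targets were lower (median -0.11, adjusted p = 0.0002, and adjusted p = 0.47 with an estimated correlation), with Id3 (-0.42), Id1 (-0.32) and Id4 (-0.28) in front. Lysosome genes were lower too (-0.09, adjusted p = 0.0006, and adjusted p = 0.9 with an estimated correlation), as were neural genes (-0.08, adjusted p = 0.0004, and adjusted p = 0.9 with an estimated correlation). ATF4 targets (0.07, adjusted p = 0.002), extraembryonic endoderm genes (-0.03, adjusted p = 0.016) and fibroblast genes (-0.08, adjusted p = 0.016) were called as well. For these the values were adjusted p = 0.9, 0.9 and 0.91 with an estimated correlation. No further list had a member that passed over the list alone.

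By limma 0 of 17639 genes passed in wild-type cells, 517 (2.93%) had an unadjusted p under 0.05, and 7% of all genes had ranges apart, where chance gives 10%. Quantile normalizing the values again gave 2 genes, Map3k5 and Galnt3, and every other setting run gave 0, array weights and the robust variance model included. Leaving out an array moved the number of called lists to 14 without separate wild-type replicate 1. The calls of the FGF and ERK and the primed lists held whichever array was left out. Without mixed wild-type replicate 1 the Myc call ended (0.15), and without mixed replicate 2 the lysosome call (0.077). The BMP call ended without separate replicate 3 (0.15), the ATF4 call without that array or mixed replicate 3 (up to 0.35). The neural (up to 0.14), endoderm and fibroblast calls (up to 0.87) ended without mixed replicate 1 or separate replicate 3.

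The co-culture change differed between the genotypes most in Fst, whose change was 2.53 lower in Bmpr1a-/- than in wild-type cells (interaction -2.53, SE 0.32, adjusted p = 0.0082). Eomes (-1.69, SE 0.26), Epha1 (-1.64, SE 0.22), Ppp4r4 (-1.63, SE 0.21), Etv4 (-1.44, SE 0.18), Nefl (-1.44, SE 0.20) and Nodal (-1.40, SE 0.26) followed. Has2, which makes hyaluronan (-1.39), Psors1c2 (-1.34) and Myc (-1.33, SE 0.22, adjusted p = 0.02) completed the 10 most negative values. The change was more positive in Bmpr1a-/- cells for Bhlhe41 (1.76, SE 0.25, adjusted p = 0.0089), Fabp3 (1.61, SE 0.29), Lrrc31 (1.51, SE 0.26), Uap1l1 (1.40, SE 0.21) and B2m (1.21, SE 0.22). BC147527 (1.19), Aqp3 (1.17), Renbp, an enzyme of amino sugar metabolism (1.16), LOC620963 (1.16) and the lipid carrier gene Apoe (1.13) came next. Smad7 (-1.24), Fgf5 (-1.08), the cyclin genes Ccnd1 (-0.82) and Ccne1 (-0.67), Hexa (1.10), Neu1 (0.80) and Rragc (0.62) passed as well.

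Of the 17 lists called in Bmpr1a-/- cells, all but p53 targets, G2 and M phase and the primitive streak were also called for the interaction. Of 18 FGF and ERK targets 7 had a lower change, none a higher one and 11 did not pass (11 lower adjusted over the list alone), with a median of -0.82 (adjusted p = 1.9e-14). Of 29 primed epiblast genes, 5 had a lower change and 24 did not pass (18 lower adjusted over the list alone), among them Sema6a (-1.26), with a median of -0.41 (adjusted p = 3.4e-16). Of 37 Myc and ribosome genes 2 had a lower change and 35 did not pass (16 lower adjusted over the list alone), with a median of -0.27 (adjusted p = 3.7e-14). Of 44 lysosome genes 4 had a higher change and 40 did not pass (20 higher adjusted over the list alone), with a median of 0.39 (adjusted p = 5.9e-17, and adjusted p = 0.098 with an estimated correlation). Lamp2 (0.99, adjusted p = 0.089) was among those that did not pass, and with the block it did. Of 19 WNT targets 2 had a lower change, Myc and Ccnd1 (5 lower and 1 higher adjusted over the list alone), with a median of -0.25 (adjusted p = 2.9e-05, and adjusted p = 0.14 with an estimated correlation). Naive genes (median 0.25, adjusted p = 6e-06, and adjusted p = 0.16 with an estimated correlation) and 2-cell genes (0.31, adjusted p = 0.0013, and adjusted p = 0.098 with an estimated correlation) had no member that passed over all genes, though 5 naive genes were higher and 1 lower, and 4 genes of the 2-cell embryo higher, adjusted over the list alone. The p53 targets were not called (median -0.07, adjusted p = 0.23), and Cdkn1a (-0.50, adjusted p = 0.18), Mdm2 (-0.37) and Trp53 (-0.29) did not pass. G2 and M phase (median 0.08, adjusted p = 0.055) and the primitive streak (-0.04, adjusted p = 0.17) were not called either. G2 and M phase was called with the block (0.035) and in 7 of the 12 fits that left out 1 array (down to 0.0035), and the streak without separate wild-type replicate 3 (0.026).

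Further lists shifted without a change that passed over all genes, except Smad7 among BMP targets, Eomes among trophoblast genes and Ccne1 among S phase genes. Those higher were BMP targets (0.11, adjusted p = 0.013), trophoblast (0.19, adjusted p = 0.0061), germ cell (0.19, adjusted p = 0.0075), hypoxia (0.17, adjusted p = 0.0081), glycolysis (0.18, adjusted p = 0.028) and neural genes (0.06, adjusted p = 0.044). Their values were adjusted p = 0.49, 0.49, 0.53, 0.42, 0.65 and 0.65 with an estimated correlation. Those lower were cholesterol synthesis (-0.22, adjusted p = 0.00018), ATF4 targets (-0.14, adjusted p = 0.0075), the unfolded protein response (-0.07, adjusted p = 0.028), S phase (-0.10, adjusted p = 0.029) and respiration (-0.06, adjusted p = 0.044). Theirs were adjusted p = 0.49, 0.65, 0.49, 0.65 and 0.65 with an estimated correlation.

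By limma 121 genes passed for the interaction, 53 with a higher and 68 with a lower change in Bmpr1a-/- cells, and 1998 had an unadjusted p under 0.05. The balance turned with array weights (115 higher and 96 lower) and without separate wild-type replicate 3 (69 and 43), and was 6 and 19 without mixed wild-type replicate 2. Of the 121, 107 also passed for co-culture in Bmpr1a-/- cells, and 120 had co-culture changes of opposite sign in the 2 genotypes. Choosing genes by the difference of the 2 changes favours both counts. No gene passed in wild-type cells, so the opposite signs do not show a response of those cells. Across all genes the 2 changes correlated at -0.21 (Pearson; -0.322 to -0.071 when 1 array was left out, weakest without separate wild-type replicate 1) and -0.14 (Spearman), and genes are not independent replicates. Of the 18 lists called, FGF and ERK targets, primed epiblast and Myc held with an estimated correlation (adjusted p = 0.03 each). With the block the first and last of these had adjusted p = 0.068 with an estimated correlation. The block gave 388 genes and kept all 121. The count was 41, 25 and 62 without mixed wild-type replicates 1, 2 and 3, and 38 and 59 without separate wild-type replicates 1 and 2. It was 36 and 35 without mixed Bmpr1a-/- replicates 2 and 3, and 70 and 60 without separate Bmpr1a-/- replicates 1 and 2. Bhlhe41, Uap1l1, BC147527, Renbp, Fst, Epha1, Ppp4r4, Etv4, Nefl, Has2, Smad7 and Sema6a, 12 of the 29 named genes that passed, held whichever array was left out. The other 17 lost their call without mixed wild-type replicate 2, and most of them without mixed wild-type replicate 1 or mixed Bmpr1a-/- replicate 3.

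Among the list calls for the interaction, the trophoblast call ended without mixed Bmpr1a-/- replicate 2 (0.13), as did the BMP call, which also ended without separate wild-type replicate 3 (up to 0.13). The germ cell call ended without separate wild-type replicate 1 (0.16). ATF4 targets lost theirs without mixed or separate wild-type replicate 3 or separate Bmpr1a-/- replicate 1 (up to 0.12). Glycolysis lost its call without mixed or separate wild-type replicate 2, mixed Bmpr1a-/- replicate 1 or separate replicate 2 (up to 0.23). The unfolded protein response lost it without mixed wild-type replicate 3, separate wild-type replicates 1 and 3, mixed Bmpr1a-/- replicate 2 or separate replicate 3 (up to 0.11). The S phase and respiration calls each held in 6 of the 12 fits that left out 1 array (up to 0.3 and 0.96), and the neural call in 4 (up to 0.3). Each of these 3 ended without separate wild-type replicate 3, mixed wild-type replicate 1, mixed Bmpr1a-/- replicate 2 or 3, or separate Bmpr1a-/- replicate 1. The S phase and neural calls also ended without separate Bmpr1a-/- replicate 3, the respiration and neural calls without mixed wild-type replicate 3, and the neural call without separate wild-type replicate 2.

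**Figure D3:**
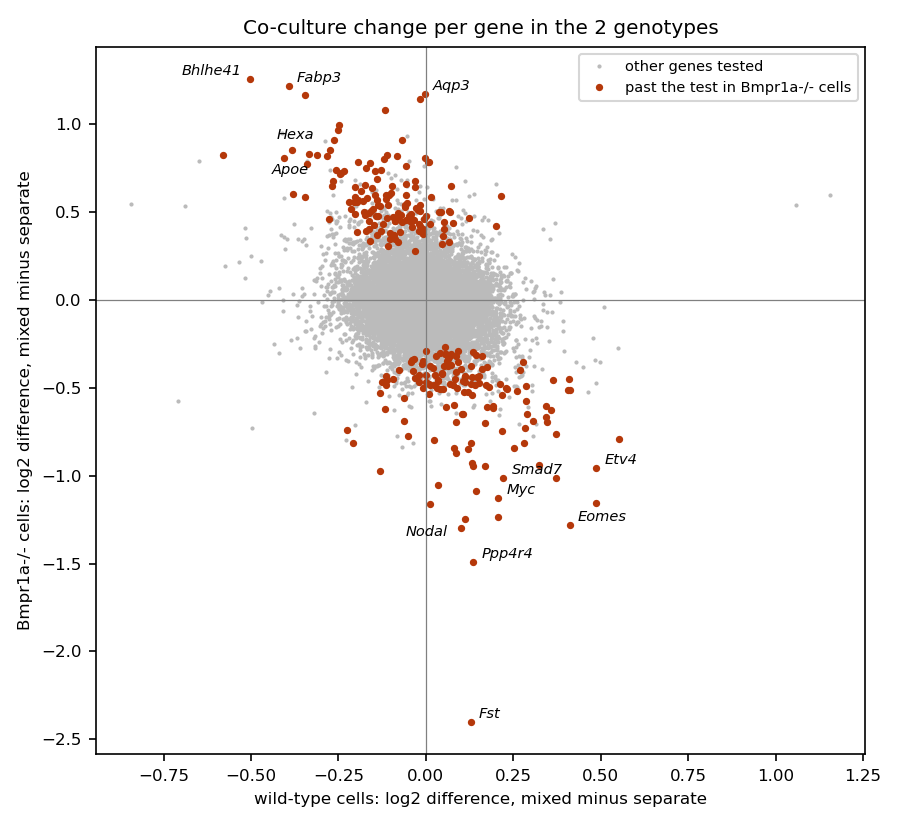
Log2 change from separate to mixed culture in wild-type cells (horizontal axis) against that in Bmpr1a-/- cells (vertical axis), with a point for each of 17639 genes and the 279 that passed in Bmpr1a-/- cells in colour. Fst lies at -2.40 and Myc at -1.13 on the vertical axis.

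Grown alone, Bmpr1a-/- cells expressed Tdgf1, Nodal and Lefty1 more highly than wild-type cells. Tdgf1, the Nodal co-receptor Cripto, was higher by 3.65 (SE 0.37, adjusted p = 0.00013), Nodal by 2.50 (SE 0.18, adjusted p = 1.8e-05; signal 352 ± 71.8 against 61.5 ± 4.09) and its inhibitor Lefty1 by 2.12 (SE 0.25). Fst was higher by 2.67 (SE 0.23) and Smad7 by 1.91 (SE 0.11, adjusted p = 1.6e-06). The naive genes Dppa5a (2.37, SE 0.35) and Zfp42 (1.5, SE 0.27) were higher, and Pou5f1 was higher by 0.75 (SE 0.08, adjusted p = 0.00025; 2990 ± 277 against 1780 ± 159). Myc (1.17, SE 0.15, adjusted p = 0.00064) and Mycn (0.67) were higher, and Sox2 (0.08), Otx2 (-0.07) and Fgf5 (0.41, adjusted p = 0.11) did not pass.

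Xist, the RNA that coats the inactive X chromosome, gave a signal of 533 to 763 in the 6 Bmpr1a-/- arrays and 23.4 to 30.4 in the 6 wild-type arrays. The 7 measured genes of the Y chromosome gave 20.1 to 25.3 in all groups, so the wild-type signals of Xist lay near the lowest the arrays give. The measured difference (4.61, SE 0.13, adjusted p = 6.2e-10) is therefore a lower bound, as are those given for Tdpoz3, Tdpoz4 and Tmem92, whose wild-type signals were as low. LOC100043292 (4.15), Trh (2.62), Efhc2 (2.32) and Tdpoz3 (2.12) were also among the 10 that the naming rule took. Lower in Bmpr1a-/- cells were the cardiac actin gene Actc1 (-1.74, SE 0.28), Greb1l (-1.63, SE 0.33), the WNT inhibitor gene Sfrp1 (-1.5, SE 0.23), Gprc5c (-1.46) and Got1l1 (-1.28). Cntd1 (-1.26), the glycolysis gene Aldoc (-1.23), the metal transporter gene Slc39a8 (-1.22), the lipase gene Lpl (-1.20) and Pttg1 (-1.16) followed.

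Of 42 measured targets of p53, 18 were higher in Bmpr1a-/- cells grown alone, 1 was lower and 23 did not pass (23 higher and 2 lower adjusted over the list alone), with a median of 0.26 (adjusted p = 1.6e-09, and adjusted p = 0.13 with an estimated correlation). Plk2 (1.13), Pml (0.98), the receptor gene Eda2r (0.89) and Pidd1 (0.80) led, and Mdm2 (0.79, SE 0.12, adjusted p = 0.0019) and Cdkn1a (0.54, SE 0.11, adjusted p = 0.0064) passed. Trp53 (0.10, adjusted p = 0.57) and Ccng1 (-0.07) did not. Of 36 apoptosis genes 6 were higher, 5 were lower, Casp8 among them (-0.73), and 25 did not pass, with no call (adjusted p = 0.36).

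Of 29 naive genes 18 were higher, 1 was lower and 10 did not pass (19 and 3 adjusted over the list alone), with a median of 0.67 (adjusted p = 7.8e-11, and adjusted p = 0.11 with an estimated correlation). Of 29 primed genes 10 were higher, 3 were lower and 16 did not pass (15 and 4 adjusted over the list alone), with a median of 0.31 (adjusted p = 1.1e-07, and adjusted p = 0.13 with an estimated correlation). FGF and ERK targets had 7 of 18 higher (11 adjusted over the list alone), Etv5 (1.02) and Etv1 (0.78) among them, with a median of 0.41 (adjusted p = 7.8e-07, and adjusted p = 0.13 with an estimated correlation). Myc and ribosome genes had 9 of 37 higher (11 adjusted over the list alone), Utp20 (0.53) and Srm (0.50) among them, with a median of 0.14 (adjusted p = 5.6e-06, and adjusted p = 0.16 with an estimated correlation). Germ cell genes had 8 of 18 higher (9 adjusted over the list alone), Rpl10l (1.69) and Mael (0.89) among them, with a median of 0.38 (adjusted p = 7.8e-07, and adjusted p = 0.21 with an estimated correlation). Of 9 genes of the 2-cell embryo 5 were higher (6 adjusted over the list alone), Tmem92 (1.31) and Tdpoz4 (1.08) among them, with a median of 0.26 (adjusted p = 9.1e-06, and adjusted p = 0.11 with an estimated correlation). Fibroblast genes had 6 of 23 lower and 1 higher (9 and 1 adjusted over the list alone), Timp2 (-1.03) and Thy1 (-0.98) among them, with a median of -0.26 (adjusted p = 0.00016, and adjusted p = 0.44 with an estimated correlation).

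In smaller shifts, the primitive streak list had 4 of 30 higher, Eomes (1.76), T (0.95) and Wnt3 (0.86) among them (4 adjusted over the list alone, adjusted p = 0.00036, and adjusted p = 0.38 with an estimated correlation). WNT targets had 6 of 19 higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.0025, and adjusted p = 0.31 with an estimated correlation), ATF4 targets 4 of 41 higher, Nupr1 (0.53) and Sesn2 (0.56) among them (6 adjusted over the list alone, adjusted p = 0.0032, and adjusted p = 0.58 with an estimated correlation). Genes that respond to dissociation and sorting had 3 of 29 higher, the chaperone gene Hspb1 (1.52) among them (6 adjusted over the list alone, adjusted p = 0.0035, and adjusted p = 0.38 with an estimated correlation). Trophoblast genes had 5 of 22 higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.023, and adjusted p = 0.58 with an estimated correlation). Neural genes had 3 of 35 lower (2 adjusted over the list alone, adjusted p = 0.04, and adjusted p = 0.82 with an estimated correlation), Zeb2 (-0.77) and Crabp2 (-0.42) among them. Of 27 BMP targets 3 were higher, Smad7, Dusp9 (1.27) and Tfap2c (0.73), and 1 was lower, Krt18 (-0.44), with no call (adjusted p = 0.37), and Id1 (-0.24), Id2 (0.25) and Id3 (-0.34) did not pass. Of the 3 higher ones, 1 was X-linked. The lysosome list had 5 higher and 5 lower of 44 and no call (adjusted p = 0.6), except without separate Bmpr1a-/- replicate 2 (0.049).

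By limma 1982 genes differed in separate culture, 872 higher and 1110 lower in Bmpr1a-/- cells, and 4292 had an unadjusted p under 0.05. More genes were higher than lower for a change of at least 1.5-fold (273 and 234), without separate wild-type replicate 2 (588 and 520) and, in a setting chosen after seeing the data, without genes of chromosomes 11 and X (657 and 599). Ranges were apart in 1948 of the 1982 and in 24.5% of all genes, where chance gives 10%. The median size was 0.45, and 92 genes differed at least 2-fold. The number of genes was 1108 without separate wild-type replicate 2 and 1085 without separate Bmpr1a-/- replicate 2. None of the 14 list calls held with an estimated correlation, while fry, which does not compare a list with other genes, called 11 lists. The ATF4 call ended without separate Bmpr1a-/- replicate 1 (0.086), the dissociation call without separate Bmpr1a-/- replicate 3 (0.08) and the trophoblast call without separate wild-type replicate 2 (0.083). The neural call ended without separate wild-type replicate 2 or 3 or separate Bmpr1a-/- replicate 1 or 3 (up to 0.25). Slc39a8 lost its call without separate Bmpr1a-/- replicate 2 (0.065), Sesn2 without that array or separate wild-type replicate 3 (up to 0.072), and Crabp2 without separate wild-type replicate 2 or separate Bmpr1a-/- replicate 3 (up to 0.11). Mycn lost it without any 1 of the separate wild-type arrays or separate Bmpr1a-/- replicate 1 or 2 (up to 0.14), and Krt18 without separate wild-type replicate 1 or 2, separate Bmpr1a-/- replicate 1 or 2, mixed Bmpr1a-/- replicate 2 or 3, or mixed wild-type replicate 1 (up to 0.16). Mael (without separate wild-type replicate 2, 0.059) and Zeb2 (without that array or separate Bmpr1a-/- replicate 3, up to 0.066) lost theirs too. The other genes named for this comparison passed whichever array was left out.

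In mixed culture Dppa5a was higher in Bmpr1a-/- than in wild-type cells by 3.07 (SE 0.35, adjusted p = 0.00011), Fbxo15 by 2.66 (SE 0.27), Zfp42 by 2.09 (SE 0.27) and Esrrb by 1.98 (SE 0.15, adjusted p = 5.3e-06). Sox2 was higher by 0.77 (SE 0.18, adjusted p = 0.0095). Hexa (1.07; signal 699 ± 86 against 334 ± 49.7), Lamp2 (1.12) and Cd63 (0.99) were higher. Etv4 (-1.04, SE 0.13, adjusted p = 0.00017), Fgf5 (-0.67, SE 0.15, adjusted p = 0.0084; 248 ± 42.7 against 394 ± 50.5) and Ccnd1 (-0.56) were lower. Myc (-0.16, adjusted p = 0.58), Pou5f1 (0.22, adjusted p = 0.11), Cdkn1a (0.04, adjusted p = 0.88) and Trp53 (-0.19, adjusted p = 0.21) did not pass, while Mdm2 did (0.43, adjusted p = 0.033).

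Among the large differences in mixed culture were LOC100043292 (5.34), Xist (4.69) and Tdpoz3 (3.10), both again lower bounds, AU018091 (3.10), Efhc2 (2.90), Tdgf1 (2.57), the imprinted RNA H19 (2.56) and LOC620963 (2.55). The lowest were Kctd12b (-1.47, SE 0.14), the peptide-processing gene Cpe (-1.34), Actc1 (-1.32), Vat1l (-1.19), the enkephalin gene Penk (-1.19) and Slc39a8 (-1.19). Igfbp4, which binds insulin-like growth factors (-1.18), Sema6a (-1.17), Spon1 (-1.17) and Pcdh18 (-1.13) followed. In the apoptosis list the caspase gene Casp8 was lower (-0.87), in a list with 3 higher, 5 lower and no call (adjusted p = 0.89).

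Of 29 naive genes 21 were higher, 1 was lower and 7 did not pass (23 and 2 adjusted over the list alone), with a median of 0.84 (adjusted p = 3.8e-17, and adjusted p = 0.031 with an estimated correlation, or 0.063 with the block). Of 44 lysosome genes 24 were higher, 1 was lower and 19 did not pass (27 and 3 adjusted over the list alone), with a median of 0.37 (adjusted p = 1.2e-12, and adjusted p = 0.21 with an estimated correlation). Of 9 genes of the 2-cell embryo 6 were higher (7 and 1 lower adjusted over the list alone), Tdpoz4 (1.90) and Usp17lc (1.88) among them, with a median of 0.51 (adjusted p = 3.3e-07, and adjusted p = 0.031 with an estimated correlation). Germ cell genes had 10 of 18 higher (12 adjusted over the list alone), Rpl10l (2.01) and Sycp3 (1.36) among them, with a median of 0.52. For that list adjusted p = 3.3e-10, adjusted p = 0.2 with an estimated correlation and 0.034 with the block as well. Targets of p53 had 12 of 42 higher and 1 lower (15 and 3 adjusted over the list alone), Eda2r (1.07) and Ephx1 (0.93) among them, with a median of 0.17 (adjusted p = 4.2e-06, and adjusted p = 0.31 with an estimated correlation). Of 31 cholesterol and lipid synthesis genes 13 were lower and 18 did not pass (17 lower and 1 higher adjusted over the list alone), with a median of -0.32 (adjusted p = 1.4e-05, and adjusted p = 0.42 with an estimated correlation). Scd2 (-0.61), Fasn (-0.55) and Scd1 (-0.53) were among these. FGF and ERK targets had 7 of 18 lower (8 lower and 1 higher adjusted over the list alone), Spred1 (-0.66) among them, with a median of -0.26 (adjusted p = 0.0085, and adjusted p = 0.4 with an estimated correlation).

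Trophoblast genes had 6 of 22 higher, Peg10 (1.42) among them (9 adjusted over the list alone, median 0.23, adjusted p = 3.8e-06, and adjusted p = 0.26 with an estimated correlation). BMP targets had 7 of 27 higher, Tfap2c (1.23) and Tbx3 (0.73) among them (8 adjusted over the list alone, median 0.04, adjusted p = 0.0016, and adjusted p = 0.4 with an estimated correlation), while Id1 (-0.13), Id2 (-0.32) and Id3 (-0.23) did not pass. The unfolded protein response had 7 of 24 lower, Hyou1 (-0.53) and Pdia6 (-0.52) among them, and 1 higher (11 and 1 adjusted over the list alone, adjusted p = 0.026, and adjusted p = 0.42 with an estimated correlation). Myc and ribosome genes had 9 of 37 lower (9 adjusted over the list alone, median -0.09, adjusted p = 0.039, and adjusted p = 0.6 with an estimated correlation), Mybbp1a (-0.43) and Ddx21 (-0.41) among them. Imprinted genes had 9 higher and 3 lower of 36 (9 and 3 adjusted over the list alone, adjusted p = 0.024, and adjusted p = 0.4 with an estimated correlation). Respiration had 5 of 54 lower and 1 higher, Uqcrq (-0.60) and Ndufa1 (0.55) among them (5 and 1 adjusted over the list alone, adjusted p = 0.039, and adjusted p = 0.73 with an estimated correlation). The higher gene was X-linked, and 1 of the 5 lower ones was on chromosome 11. As given below, these chromosomes differ as a whole between the lines. G2 and M phase had 2 each way (adjusted p = 0.032, and adjusted p = 0.62 with an estimated correlation), the 2 lower ones on chromosome 11. Calls near the threshold were those of ribosomal protein genes (0.042, and 0.052 with the block), dissociation and sorting (0.043, and 0.054), fibroblast genes (0.04, and 0.054) and the primitive streak (0.043, and 0.054). For these 4 lists the values were adjusted p = 0.6, 0.6, 0.62 and 0.62 with an estimated correlation. Of 29 primed genes 7 were higher and 10 lower, with no call (adjusted p = 0.45), a median of -0.13 and a mean of 0.07.

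By limma 2905 genes differed in mixed culture, 1121 higher and 1784 lower in Bmpr1a-/- cells, and 4963 had an unadjusted p under 0.05. For a change of at least 1.5-fold the balance turned (439 higher and 357 lower). Ranges were apart in 2876 of them and in 32.7% of all genes, where chance gives 10%. The median size was 0.44, and 169 differed at least 2-fold. The count was 1853 without mixed Bmpr1a-/- replicate 2. Of the 18 list calls, those of the naive and the 2-cell lists held with an estimated correlation, and fry called 13 lists. Without mixed wild-type replicate 1 or mixed Bmpr1a-/- replicate 3 the Myc call ended (up to 0.2), and without mixed wild-type replicate 3 that of the unfolded protein response (0.068). Without mixed wild-type replicate 2 the G2 and M phase call ended, as it did without mixed Bmpr1a-/- replicate 3 (up to 0.24). The respiration and streak calls ended without mixed wild-type replicate 1 or 3 or mixed Bmpr1a-/- replicate 2 or 3 (up to 0.25 and 0.14). The fibroblast call ended without mixed wild-type replicate 2 or 3 or mixed Bmpr1a-/- replicate 1 (up to 0.13), and the ribosomal call without mixed wild-type replicate 1 or 2 or mixed Bmpr1a-/- replicate 3 (up to 0.24). The dissociation call also ended without each of these last 3, mixed Bmpr1a-/- replicate 1 or separate wild-type replicate 3 (up to 0.29). Slc39a8 lost its call without mixed wild-type replicate 3 or mixed Bmpr1a-/- replicate 2 (up to 0.055), and Mdm2 without any 1 of the mixed arrays except Bmpr1a-/- replicate 3 (up to 0.12). Ndufa1 lost it without mixed wild-type replicate 2 (0.054).

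The genotype difference was called in both cultures for 1158 genes, of which 1143 had the same direction, while 824 were called in separate and 1747 in mixed culture alone. Across all 17639 genes the 2 differences correlated at 0.69 (Pearson) and 0.54 (Spearman), with a slope of 0.79. Chromosome 11 and the X chromosome stood apart. Of 570 genes of chromosome 11 with a mean log2 signal of at least 7, 93.7% were lower in Bmpr1a-/- cells in separate and 89.6% in mixed culture, with medians of -0.31 and -0.41. Of the lower calls, 369 of 1110 in separate and 487 of 1784 in mixed culture were on chromosome 11, which held 1385 of the genes tested. The 233 X-linked genes had medians of 0.24 and 0.28, and 120 of 872 and 150 of 1121 higher calls were X-linked. The 18 other autosomes had medians from -0.06 to 0.03 in separate and from -0.16 to -0.01 in mixed culture. Lower calls of lists included genes of chromosome 11, in mixed culture 2 of 13 in the cholesterol list, 2 of 7 in the FGF and ERK list, 3 of 9 in the Myc list and 2 of 2 in the G2 and M phase list. Higher calls included X-linked genes, in mixed culture 2 of 2 in the ribosomal protein list, 3 of 24 in the lysosome list and 1 of 7 in the BMP list. Other lists held such genes as well. In the co-culture comparison of Bmpr1a-/- cells the median of chromosome 11 was -0.08, and those of the other autosomes ran from -0.07 to -0.02.

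**Figure D4:**
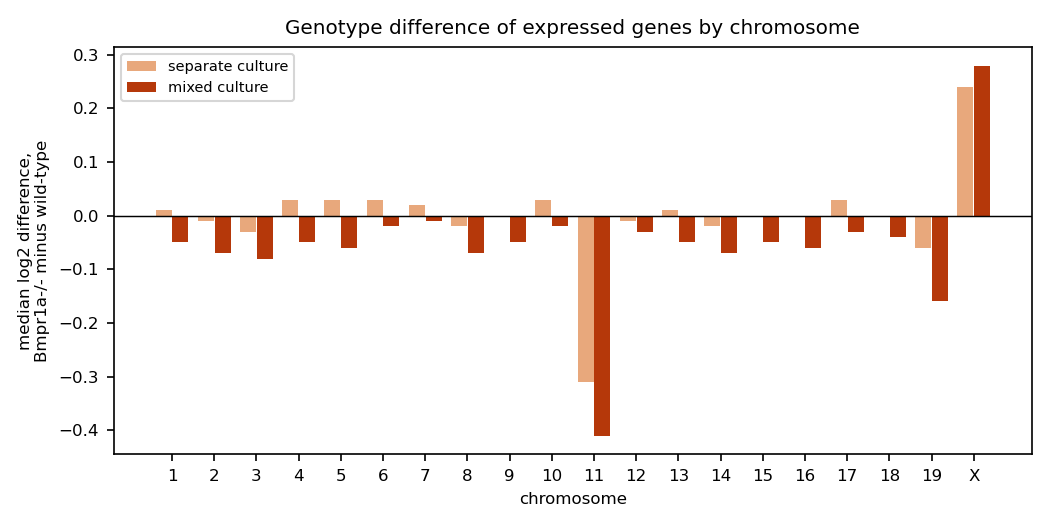
Median log2 difference between Bmpr1a-/- and wild-type cells of the genes of each chromosome, in separate and in mixed culture, with bars for medians of genes with a mean log2 signal of at least 7. Chromosome 11 lies at -0.31 and -0.41 and the X chromosome at 0.24 and 0.28.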

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

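Several tests were chosen after the co-culture change was seen. They were those of wild-type cells in the sorted fraction, of shared handling, of falls on a held-out array and of the covariance across genes. The same holds for the block made from the within-group component. The planned rule for splits counted all of them, without the restriction to those that part the replicate numbers. The predictions of the other tests were written before those tests were run. The comparisons set beforehand named no chromosome, so chromosome 11 was taken up for its values in these data.

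The co-culture change differed between Bmpr1a-/- and wild-type cells, in a test of the difference itself, for 121 genes. The 20 with the largest difference among these had values (log2 change in Bmpr1a-/- minus that in wild-type cells) of 1.76 for Bhlhe41, 1.61 for Fabp3, 1.51 for Lrrc31, 1.40 for Uap1l1, 1.21 for B2m, 1.19 for BC147527, 1.17 for Aqp3, 1.16 for Renbp, 1.16 for LOC620963 and 1.13 for Apoe. On the negative side they were -2.53 for Fst, -1.69 for Eomes, -1.64 for Epha1, -1.63 for Ppp4r4, -1.44 for Etv4, -1.44 for Nefl, -1.40 for Nodal, -1.39 for Has2, -1.34 for Psors1c2 and -1.33 for Myc. The same test separated the genotypes for 18 lists, with medians of 0.39 for the lysosome, 0.31 for the 2-cell embryo, 0.25 for the naive state, 0.19 for germ cells, 0.19 for trophoblast, 0.18 for glycolysis, 0.17 for hypoxia, 0.11 for BMP targets and 0.06 for neural genes. They were -0.82 for FGF and ERK targets, -0.41 for the primed epiblast, -0.27 for Myc and ribosome production, -0.25 for WNT targets, -0.22 for cholesterol synthesis, -0.14 for ATF4 targets, -0.10 for S phase, -0.07 for the unfolded protein response and -0.06 for respiration. As in the report, 3 of these lists were called with an estimated correlation.

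A signal also appeared in probe sets that carry several gene symbols and that no comparison of the report used. For co-culture in Bmpr1a-/- cells 61 of 1885 of them passed, 55 higher and 6 lower, and none passed by limma in wild-type cells. For the interaction 1 passed, so the change is not shown to differ between the genotypes. Among the higher ones, chosen after their values were seen, were the oocyte homeobox family of Obox4 (1.16), the family of Pramel12 (1.04) and a probe set shared by Kitl (1.03), and several probe sets often cover the same family. Between genotypes 195 differed in separate culture (150 higher, 45 lower) and 322 in mixed culture (221 higher, 101 lower). Of 2111 probe sets without a symbol, none passed by limma for co-culture in either genotype.

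For the interaction, 4 of 100 splits drawn from the 200 of the arrays within each genotype called as many genes as the real one, the real one included, a share under 0.05. Of the 100, however, 38 part the 3 replicate numbers of the Bmpr1a-/- arrays as the real one does, and 2 of these called as many, the real one included (highest other 209), a share over 0.05. Chance can therefore not be excluded for this count once the pairing is kept. Among the splits that do not part them, 1 called 1708 genes, many times the 121 of the real one. Its sides were those of the leading component of the deviations within groups, for all 12 arrays, which held 38.9% of the variance within groups. With that side as a block 326 genes passed, and a block taken from the deviations themselves shrinks the spread. The sides followed the spread of signal of the arrays. The upper quartile of signal was 176.79 to 180.25 on the arrays of one side and 166 to 176.7 on those of the other. Replicate 1 of every group lay on the first side and replicate 3 of every group on the second. What caused this is not given in the labels and was not tested.

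The co-culture change in Bmpr1a-/- cells was weighed against wild-type cells left in the sorted fraction. Genes over 4-fold higher in Bmpr1a-/- than in wild-type cells grown alone (10 genes, chosen without the mixed arrays) would then fall by the wild-type share. Of the 140 called falls, 107 had a lower signal in mixed wild-type than in separate Bmpr1a-/- cells. These needed a median wild-type share of 143.3%, more than a mixture can hold. A share just under 100% needed a median change of -2.5 in these genes, and it was -0.27. The SE of the mean gap, 0.48, came from the spread over the 10 genes. Genes are not replicates, so it does not measure the spread between arrays. The comparison sets the genes against a fraction made almost wholly of wild-type cells, and not against a smaller share. Fst fell nearly as far as needed (-2.40 against -2.55). The other 9 lay above the change needed by over 2 SE of each gene's own change. They ran from Nodal (-1.30 against -2.36) to LOC100043292 (0.9 against -4.15), with Xist (0.03, SE 0.13, against -4.35) among them. Of the 279 called genes, 183 (65.6%) lay outside all 9 other arrays, where a mixture alone does not bring group means. Of all genes tested 7.6% did, which is no like reference. All 279 already lay apart from the 3 separate Bmpr1a-/- arrays, as 18% of all genes did. The share needed and the values of the 10 genes argue against wild-type cells as the only source of the falls. A smaller wild-type share was not tested, and noise can also place a gene outside the other arrays.

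Handling shared by both mixed populations, such as the sort, would move the same genes in mixed wild-type cells. Signed by the direction in Bmpr1a-/- cells, the median change of the called genes in wild-type cells was -0.10 (quartiles -0.18 to -0.03), against a median size of 0.50 in Bmpr1a-/- cells. Of the 279, 44 moved in the same direction and 235 in the opposite one, which argues against a shared cause. A response of the GFP-marked line alone to sorting, and a response of Bmpr1a-/- cells to their neighbours, may both give such a pattern and remain open, since each mixed Bmpr1a-/- array was both mixed and sorted.

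For that change the 6 arrays make 10 splits, too few for a share under 0.05. The real split gave 279 genes, as large as 1 of 10 splits, and the highest other gave 0, among the 4 splits that part all 3 replicate numbers as the real one does and among the rest. In wild-type cells the real split gave 0 genes, matched or passed by 10 of 10 splits, and the highest other gave 1. In the genotype comparisons the real splits gave 1982 and 2905 genes, each as large as 1 of 10 splits, and the highest other gave 0 in both.

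Genes that fell in co-culture were often higher in Bmpr1a-/- cells grown alone. Of 140 falls 66 were among the 872 higher in separate culture, where independent calls would give 6.92, and 2 among the lower, against 8.81. Of 139 rises 34 were among the higher, against 6.87, and 16 among the lower, against 8.75. Both comparisons use the same separate Bmpr1a-/- arrays, which would tie falls to higher and rises to lower values, so they do not explain the 34 rises. They also share 1 estimate of the spread per gene, with which a gene of small spread can pass in both, in any direction. The numbers for independent calls leave this out, so the size of the excess cannot be read from them. The covariance of the 2 differences across genes was -0.00592. In 100 simulations of unchanged groups with the measured spread it ran from -0.00688 to -0.00591, and with a correlation of 0.3 between mixed and separate Bmpr1a-/- arrays of equal number, the mean found, from -0.00482 to -0.00408. The first range holds the value and the second does not, so it stays open whether shared arrays account for the relation across all genes. For the falls, those called without 1 separate Bmpr1a-/- array were measured on that array, against separate wild-type cells. Their medians were 0.38, 0.75 and 0.12 (all genes 0, -0.05 and -0.03; rises 0.14, 0.2 and 0.15), above all genes by 0.44 on average (SD 0.33 between the 3 arrays) and by 0.15 at the lowest. The spread between the arrays keeps open whether shared arrays account for the falls. For the 66 genes the median genotype difference was 0.63 in separate and -0.07 in mixed culture, and 6 of them were still higher and 9 lower in mixed culture. They were chosen as higher in separate culture and falling in co-culture. A smaller difference in mixed culture therefore follows in part from the choice and is no separate evidence.

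Genes of chromosome 11 were lower in Bmpr1a-/- cells in both cultures, a pattern taken up after it was seen. Of 10000 random sets matched on signal, none had as low a median, and the lowest was -0.04 in separate and -0.10 in mixed culture, against -0.31 and -0.41. This argues against the signal level or the normalization as the source. A copy difference between the lines would lower each part of the chromosome alike, and the 3 equal parts of its genes in order had medians from -0.32 to -0.31 in separate and from -0.43 to -0.38 in mixed culture. The lowest of 54 such parts of other autosomes was -0.11 and -0.17. These values are consistent with fewer copies of chromosome 11 in the Bmpr1a-/- line or more in the wild-type line, a hypothesis that expression alone cannot settle, and no biological effect of the genotype on this chromosome was tested.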

How the results depend on the processing

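The block made from the within-group component and the setting without chromosomes 11 and X were chosen after seeing the data, and the other settings were planned.

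Co-culture in Bmpr1a-/- cells gave 279 genes, and 163 after quantile normalizing again, 46 with only the groups compared (fewer arrays behind the spread), 455 with array weights, 104 with a change of at least 1.5-fold (a stricter threshold), 879 with the replicate block and 504 with the component block. In wild-type cells the count was 0, and 2 after quantile normalizing again. The interaction gave 121, and 388 with the replicate block, 211 with array weights and 326 with the component block. Genotypes differed in separate culture for 1982 genes, and for 1172 with only the groups compared, 507 at 1.5-fold and 1256 without genes of chromosomes 11 and X. In mixed culture they differed for 2905, and for 796 at 1.5-fold. Except where fewer genes, fewer arrays or a stricter threshold show it, the cause was not tested. The other settings, apart from leaving out arrays, kept each count of genes within 1.5 times.

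Camera called 17 lists for co-culture in Bmpr1a-/- cells, 4 with an estimated correlation, and fry called 6. In wild-type cells these were 9, 0 and 0, for the interaction 18, 3 and 6. With an estimated correlation 0 of 14 were called for genotype in separate and 2 of 18 in mixed culture, where the filter at the 40th percentile left 10. Fry called 11 lists for genotype in separate and 13 in mixed culture. The correlation of the 2 genotype differences was 0.688, and 0.647 without chromosomes 11 and X.

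Leaving out each array in turn gave 50 to 391 genes for co-culture in Bmpr1a-/- cells and 25 to 132 for the interaction. It gave 1085 to 1968 for genotype in separate and 1853 to 3124 in mixed culture, with 0 throughout for co-culture in wild-type cells. Lists called in wild-type cells ranged from 6 to 14. The correlation of the 2 genotype differences ranged from 0.636 to 0.719, and that of the 2 co-culture changes from -0.322 to -0.071. The test's direction turned for 2 lists with no call in wild-type cells. The germ cell median ranged from -0.081 to 0.056 and the list was called higher without separate wild-type replicate 1. The respiration median ranged from -0.105 to 0.03. That list was called lower without separate wild-type replicate 3 and higher without mixed wild-type replicate 2. The cause was not tested.

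Of 17114 values of 696 results for named genes under the alternatives, 16214 kept direction and side of the threshold, 618 fell short of it, 282 newly passed and 0 turned. Of 3994 values for lists, 3658 kept both, 260 fell short, 74 newly passed and 2 turned.

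Pairing by replicate number was not borne out between mixed and separate wild-type cells (correlations 0.57, -0.10 and 0.14) or between the separate cultures (0.06, 0.05 and 0.34). With the block 9 lists were called in wild-type cells. For genotype in separate culture 15 were, ribosomal protein genes joining at adjusted p = 0.046, and 2 held with an estimated correlation, the primed epiblast (0.039) and the 2-cell embryo (0.044). The block kept 1981 of the 1982 and 2901 of the 2905 genes, and beyond the calls named here and in the report it changed none that the report gives. Genes with a mean signal under 25.3 were not tested, so low expression limits what these arrays can show.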

Other observations

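This part gives values, calls and p-values of the comparisons set beforehand. Its genes outside the naming rule were chosen after their values were seen.

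Of 25 interferon response genes 3 were higher and 2 lower in Bmpr1a-/- cells in each culture, and the list was called in neither (adjusted p = 0.95 in separate and 0.45 in mixed culture). Of 36 imprinted genes, which are expressed from 1 parental copy, 6 were higher and 5 lower in separate culture, without a call (adjusted p = 0.11), and 9 and 3 in mixed culture (adjusted p = 0.024, and adjusted p = 0.4 with an estimated correlation). Among these, H19 was higher in Bmpr1a-/- cells by 1.43 (SE 0.27) in separate and 2.56 (SE 0.27) in mixed culture. Peg10 was higher by 0.97 (SE 0.25) and 1.42 (SE 0.25), Igf2r by 1.25 (SE 0.15) in mixed culture, and Nnat was lower in separate culture (-0.79, SE 0.12). Of interferon response genes, Ifitm3 was higher by 1.22 (SE 0.21) and 1.46 (SE 0.21) and Ifitm1 by 0.76 (SE 0.20) and 1.98 (SE 0.20). B2m was lower in separate culture (-0.91, SE 0.15). In separate culture Peg10 did not pass without separate wild-type replicate 1 or 2 or separate Bmpr1a-/- replicate 2 or 3 (adjusted p up to 0.10). Ifitm1 did not pass without separate wild-type replicate 2 or 3 or separate Bmpr1a-/- replicate 1 or 2 (up to 0.093). The chaperone gene Hspb1 was higher in both cultures, by 1.52 (SE 0.18) and 1.95 (SE 0.18).

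Of the genes called in both cultures 15 differed between genotypes in opposite directions. Higher in Bmpr1a-/- cells alone and lower in the mix were the ephrin receptor gene Epha1 (0.87 and -0.77), the hyaluronan synthase gene Has2 (0.94 and -0.45), the neurofilament gene Nefm (0.66 and -0.44) and the kinase gene Dclk1 (0.34 and -0.64). The same held for Grik3 (0.51 and -0.43), Map7d3 (0.50 and -0.41), Zfp365 (0.42 and -0.45) and Pop1 (0.26 and -0.26). Dusp6 (0.65 and -0.37) and Il17rd (0.56 and -0.25), both inhibitors within the FGF pathway, did so too. The reverse held for Zfp516 (-0.47 and 0.64), Mospd1 (-0.43 and 0.49), Scrn1 (-0.49 and 0.43), Tmem106b (-0.35 and 0.43) and Dtna (-0.27 and 0.49). Each of the 15 passed for the interaction, with adjusted p from 0.0082 for Il17rd to 0.04 for Grik3. The interaction equals the mixed minus the separate genotype difference. Passing it thus follows largely from how the 15 were chosen and is no separate evidence.

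The probe set shared by Nanog and a pseudogene was higher in Bmpr1a-/- cells by 0.66 (SE 0.20, unadjusted p = 0.0086 by limma) in separate and 0.92 (SE 0.20, unadjusted p = 0.0011) in mixed culture. Its change in co-culture was -0.10 in Bmpr1a-/- cells (unadjusted p = 0.62) and -0.36 in wild-type cells (unadjusted p = 0.11). Because the probes do not separate the copies, the values cannot be assigned to Nanog alone.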
